A study of Homo sapiens with 4 samples.

How the data were processed

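Chromatin of HepG2 cells, an established human liver cancer line, was crosslinked with 1% formaldehyde for 10 min and immunoprecipitated with 1 antibody per library, against SMRC1, SATB1 or NFIC. The labels also name an input library, for which no peak list or signal was analysed here. Each antibody had 1 library, so the 3 peak lists have no replicates, and every interval and test over peaks describes these libraries and not the spread between experiments.

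Per the submitters' processing notes, the build was hg19 and the tools were Bowtie 1.1.2, SAMtools, MACS2 2.1.1 and deepTools. The settings of these tools, and which library served as control, are not given in the sources used here. Each deposited list has 10 columns in narrowPeak order and no header. The deposited score of a peak was 10 times its −log10 q rounded down, except in 2 SMRC1 peaks. The deposited fold is the authors' ratio of the reads at the summit to the local background. The deposited −log10 p and −log10 q are those of the authors' peak caller, and the lowest −log10 q was just above 1 in each list, which corresponds to a q-value bound of 0.1. These values served to describe, rank and filter peaks and to compare folds and ranks between lists. The fold and the p-value also served to recover reads and background, as described below. The peaks on chromosome 1 reached position 249200736, within the hg19 length of 249250621.

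The reads at each summit and the local background were recovered by solving the MACS2 expressions for the fold and the Poisson p-value together, with reads taken as whole within 0.05. This gave a solution in 100% of SMRC1 and SATB1 peaks and in 13640 of 13643 NFIC peaks. The factors by which libraries were scaled gave a ChIP depth relative to the control of 1.29 for SMRC1, 0.877 for SATB1 and 1.01 for NFIC. For SATB1, where the control was the scaled library, the factor was found by 2 scans. A first scan, by a cosine score, gave 0.878, and at that factor 0% of backgrounds below 15 were whole multiples within 0.002. A scan for whole multiples replaced it after its values had been seen, gave 0.877, and made 43.9% of them whole. Background is given in unscaled control fragments. Its lowest value was 1.40, 1.38 and 1.38 control fragments in the SMRC1, SATB1 and NFIC lists, so the 3 lists appear to rest on the same or an equally deep control. That is an inference from the values, and it assumes the same fragment length in the 3 lists, which was not determined. Fragment lengths and total read numbers were also sought in the steps of the background. A length and its fraction fitted about equally well and the choice set the total, so neither is reported and the absolute depth is unknown.

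Peaks were taken as overlapping when they shared at least 1 bp. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. Overlaps were compared with 1000 random placements of the peaks within their chromosomes, outside centromeric, variable and stalk bands, with a one-sided permutation p whose smallest value is 0.001. Shared and other peaks were compared by the difference in median percentile rank, with a two-sided permutation test of 100000 permutations whose smallest p is 1e-05. Conditional shares were compared by two-sided Fisher's exact tests and by Mantel-Haenszel odds ratios within deciles of peak strength (−log10 q) or of width. Correlations have Benjamini-Hochberg adjusted permutation p-values. Medians have bootstrap 95% intervals from 2000 draws. Positions are 1-based. Chromosome lengths came from GenomeInfoDb 1.38.1 and chromosome bands from circlize 0.4.16, both for hg19. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

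The overlap test was tested on simulated lists of 3296 peaks against the NFIC list. It gave p under 0.05 for 0 of 20 random lists and found 316 of 316 overlaps in a list with planted sites. The random lists came from the same placement as the test. The outcome therefore checks the calculation and not whether that placement suits clustered peaks. The recovery of reads was tested on 3000 simulated peaks at each of 2 scales and found 100% of reads and backgrounds. The scan for the factor of a scaled control, used for SATB1, was not part of that simulation.

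Peaks named in the results were chosen by a rule fixed before the data were examined, as the 10 peaks of each library with the highest −log10 q and the 10 sites shared by all 3 libraries with the lowest sum of ranks. Peaks and regions named under the other observations were chosen after their values were seen. The rule first asked for genes at promoters. No hg19 gene annotation or genome sequence was used here, so promoters, motifs and gene lists, 3 of the 9 planned kinds of result, were not analysed here, and no peak was assigned to a gene. A gene table of the assembly GRCh38.p14 served only to count protein-coding genes per chromosome. The other settings tried were a −log10 q of at least 10, merging peaks within 500 bp, coverage of 50% of the shorter peak, centres within 200 bp, and ranking by width. Further settings were added after seeing the data. These were moving peaks by 10 to 50 kb, equal numbers of peaks per list, leaving out centromeric and variable bands, ranking by fold, and leaving out chromosomes 2, 6, 14, 16, 17 and 20.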

Results

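ChIP-seq peak lists were examined from HepG2 cells, an established line derived from a human liver tumour, for 3 chromatin-associated proteins. SMRC1 is the database entry name of SMARCC1 (BAF155), a core subunit of the SWI/SNF chromatin remodelling complexes. SATB1 is a DNA-binding protein that organises chromatin at AT-rich sequence, and NFIC is a transcription factor of the nuclear factor I family. The study set out to compare profiles obtained with its own antibodies with published profiles from commercial ones. The published profiles were not used here, and the comparisons below are among the 3 lists, each from 1 library. There were no replicates, so no difference between antibodies could be set against a replicate spread.

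The SMRC1 library had the most sites. Its list held 29441 peaks covering 20.5 Mb, against 13643 peaks covering 7.25 Mb for NFIC and 3296 peaks covering 1.52 Mb for SATB1. The SMRC1 list was thus 2.16 times as long as the NFIC list and 8.93 times as long as the SATB1 list. SMRC1 peaks were also the widest, with a median of 607 bp (quartiles 433 and 841), compared with 490 bp (382 and 629) for NFIC and 399 bp (339 and 520) for SATB1. The authors' fold over background had a median of 4.87 for NFIC, 4.08 for SMRC1 and 3.54 for SATB1. Peaks with a −log10 q of at least 10 made up 46.3% of the NFIC list, 43.7% of the SMRC1 list and 13.8% of the SATB1 list. The median summit held 45 reads for SMRC1 and 32 reads for NFIC and for SATB1. Relative to the control, the SMRC1 library was the deepest (1.29), followed by NFIC (1.01) and SATB1 (0.877), and the number of peaks called depends on depth. This order holds between the libraries only if their controls were equally deep. At a −log10 q of at least 10 the lists held 12871, 6314 and 456 peaks for SMRC1, NFIC and SATB1.

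The highest-ranked SMRC1 peak lay on chromosome 5 at 137673081 to 137674381 (hg19, band q31.2), with a fold of 28.1 and 374 reads at its summit. The next lay on chromosome 11 at 65686132 to 65687319 (q13.1, fold 22.1) and on chromosome 3 at 50358490 to 50359702 (p21.31, fold 22.3). In the SATB1 list the leading peaks were on chromosome 2 at 174219022 to 174220050 (q31.1, fold 28.6), chromosome 1 at 228674377 to 228675408 (q42.13, fold 22.6) and chromosome 10 at 63660811 to 63661519 (q21.2, fold 25.1). The NFIC list was led by peaks on chromosome 13 at 113950944 to 113951992 (q34, fold 38.9), chromosome 7 at 4814783 to 4815740 (p22.1, fold 40.3) and chromosome 7 at 915634 to 916580 (p22.3, fold 28.9). All of the 10 highest-ranked NFIC peaks overlapped an SMRC1 peak, against 51.9% of the whole list (Fisher's exact test, two-sided, p = 0.0021). Of the 10 highest-ranked SATB1 peaks, 7 overlapped an SMRC1 peak (exact p = 0.46) and 0 overlapped an NFIC peak, against 27.4% of the whole SATB1 list (exact p = 0.071). Of the 10 highest-ranked SMRC1 peaks, 3 overlapped a SATB1 peak, against 8.61% of the list (exact p = 0.048), and 3 an NFIC peak (exact p = 0.71). For NFIC, 2 of the 10 overlapped a SATB1 peak (exact p = 0.14). These 6 tests were not corrected for their number, and they depend on the number of peaks taken. With 12 peaks, a number chosen after seeing the data, 0 SATB1 peaks were at NFIC sites (exact p = 0.045) and 9 at SMRC1 sites (exact p = 0.73). Of 12 SMRC1 peaks, 5 were at SATB1 sites (exact p = 0.0022) and 3 at NFIC sites (exact p = 1), and of 12 NFIC peaks, 11 were at SMRC1 sites (exact p = 0.0067) and 2 at SATB1 sites (exact p = 0.18).

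Sites of the 3 proteins coincided far more often than random placement gave. Most SATB1 peaks, 2586 of 3296 (78.5%, 95% interval 77.0 to 79.9), overlapped an SMRC1 peak, where random placement gave 47.9 ± 6.94 (SD over placements), a 54.0-fold excess. Of the NFIC peaks, 7074 of 13643 (51.9%, 51.0 to 52.7) lay at SMRC1 sites, against 197 ± 13.3 at random, a 35.8-fold excess. SATB1 peaks overlapped NFIC peaks in 902 cases (27.4%, 25.8 to 28.9), against 19.3 ± 4.24 at random, a 46.6-fold excess. Each permutation p was 0.001, the smallest that 1000 placements can give. Summits of overlapping peaks lay close together, at a median distance of 85 bp for NFIC and SMRC1, 85 bp for SATB1 and SMRC1, and 110 bp for SATB1 and NFIC. When peaks were moved by 10 to 50 kb, a setting added after seeing the data that keeps regional density, the excess was 23.4-fold for SATB1 at SMRC1 sites, 14.6-fold for NFIC at SMRC1 sites and 20.9-fold for SATB1 at NFIC sites. The lists appear to rest on the same or an equally deep control, and if it was the same, part of the excess could come from it. Chromatin open to ChIP in any library could also raise the overlap, since neither kind of placement matched it. The excess therefore does not separate binding at the same sites from such general effects. With equal numbers of peaks per list, a setting added after seeing the data, the shares fell to 20.2% for SATB1 at SMRC1 sites, 20.1% for NFIC at SMRC1 sites and 8.71% for SATB1 at NFIC sites.

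**Figure D1:**
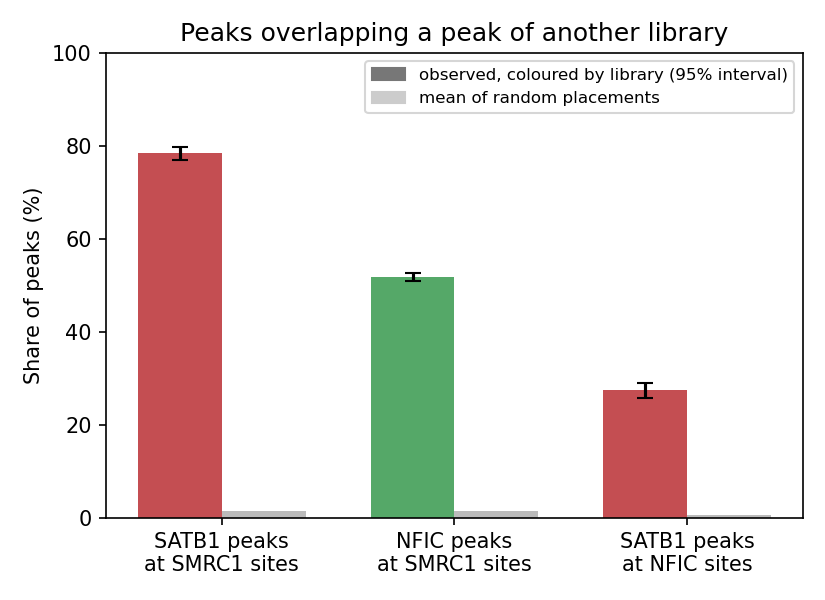
Share of peaks (%) of one library that overlapped a peak of another, with exact 95% intervals, beside the mean share over 1000 random placements in grey. Observed shares were 78.5%, 51.9% and 27.4%, and the random shares were 1.45%, 1.45% and 0.587%.

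Sites common to all 3 libraries comprised 854 SATB1 peaks (25.9%, 24.4 to 27.4), against 9.81 ± 3.21 at random, an 87.0-fold excess (permutation p = 0.001, the smallest possible), and 36.9-fold when peaks were moved by 10 to 50 kb. The shared site with the lowest sum of ranks lay on chromosome 10 at 60228322 to 60228716 (q21.1), with folds of 23 for SMRC1, 20.7 for NFIC and 4.78 for SATB1. It was followed by sites on chromosome 14 at 39901791 to 39902140 (q21.1) and at 35873271 to 35874303 (q13.2). Another, on chromosome 6 at 155649964 to 155650334 (q25.3), lay in an SMRC1 peak of fold 17.6. Other sites among the leading 10 were on chromosomes 16 (q12.1), 2 (q11.2 and p16.2), 9 (q22.32), 10 (p12.1) and 6 (p21.2). Many sites belonged to 1 list alone, which was the case for 20821 SMRC1 peaks (70.7%), 6520 NFIC peaks (47.8%) and 662 SATB1 peaks (20.1%).

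Sharing between SATB1 and NFIC was concentrated at SMRC1 sites. Of the SATB1 peaks at SMRC1 sites, 33.0% also had an NFIC peak, compared with 6.76% of the SATB1 peaks elsewhere (odds ratio 6.80, exact p = 4.7e-53). Of the NFIC peaks at SMRC1 sites, 11.9% had a SATB1 peak, compared with 0.746% elsewhere (odds ratio 18, exact p = 1.3e-184). SMRC1 peaks with an NFIC peak had a SATB1 peak in 12.7% of cases and those without in 7.33% (odds ratio 1.85, exact p = 1e-41). Within deciles of the strength of the peaks compared, the odds ratio was 6.69 for SATB1 peaks, 17.1 for NFIC peaks and 1.12 (1.02 to 1.23) for SMRC1 peaks. These deciles were of −log10 q and not of background. The median background of SATB1 peaks was 10.198 control fragments at SMRC1 sites and 5.001 elsewhere, and that of NFIC peaks 9 and 3.388. The odds ratios for SATB1 and NFIC peaks therefore do not separate sharing at SMRC1 sites from general effects such as chromatin open to ChIP. The p-values are from two-sided Fisher's exact tests over peaks, which are not independent replicates.

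Sharing of SMRC1 sites rose with their strength when taken by decile, although 3 of the 10 highest-ranked SMRC1 peaks had an NFIC peak. From the lowest to the highest decile of SMRC1 peaks by −log10 q, the share with an NFIC peak went from 8.62% (7.64 to 9.70) to 66.1% (64.4 to 67.8), and the share with a SATB1 peak from 2.55% (2.01 to 3.18) to 19.1% (17.7 to 20.6). Shared SMRC1 peaks lay 32.6 percentile points above the other SMRC1 peaks in median rank by −log10 q. The difference was 17.7 points for SATB1 and 5.72 points for NFIC (permutation tests, each p = 1e-05, the smallest possible). For NFIC, the share at SMRC1 sites lay between 47.4% and 53.6% in the lower 9 deciles and was 66.7% in the highest. Ranked by fold, a setting added after seeing the data, the difference stayed positive for SMRC1 (24.5 points) and turned negative for SATB1 (-23.7) and NFIC (-26.4).

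**Figure D2:**
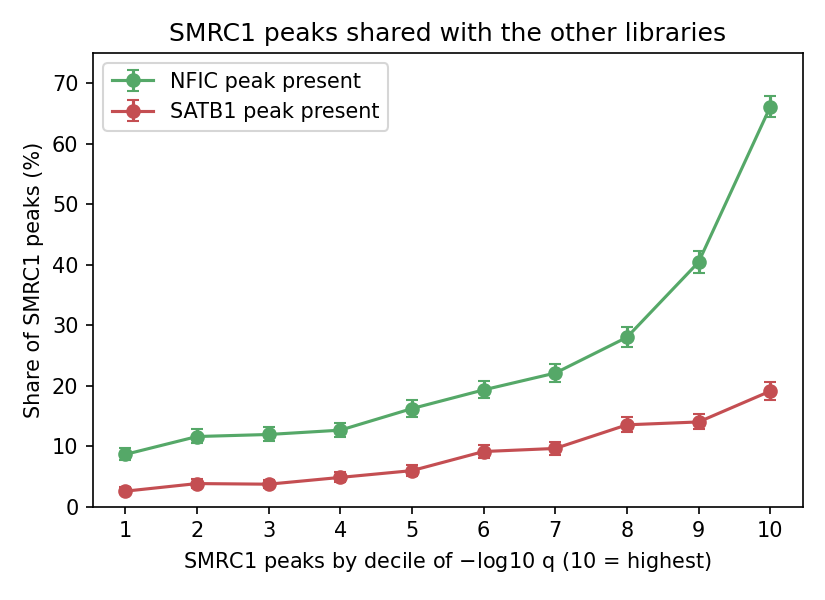
Share of SMRC1 peaks (%) with an NFIC or a SATB1 peak, by decile of SMRC1 −log10 q, where 10 is the highest; bars are exact 95% intervals. The share with NFIC reached 66.1% and the share with SATB1 19.1% in the highest decile.

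Fold values at shared sites were only weakly related. Across SATB1 peaks at SMRC1 sites, Pearson's r of log2 fold was 0.17 and Spearman's rho 0.18 (each adjusted permutation p = 2e-05). For SATB1 with NFIC, r was 0.12 (adjusted permutation p = 0.0004) and rho 0.16 (2e-05), and for NFIC with SMRC1, r was 0.025 (0.032) and rho 0.042 (0.00044). These 3 relations are across peaks, which are not independent replicates. If the lists share a control, both folds at a site have nearly the same background as denominator. That alone could give a positive correlation, and the permutation does not remove it. The values therefore do not show that binding strengths are related.

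Light-staining, gene-rich chromosome bands carried most sites in each library. Unstained bands had 3.32 times the SMRC1 peaks per Mb of the darkest bands, 3.11 times the NFIC peaks and 4.95 times the SATB1 peaks. Among bands of at least 2 Mb, the densest for SMRC1 was 17q21.2, with 100 peaks (40 per Mb). For SATB1 it was 17q25.3, with 52 peaks (8.82 per Mb), and for NFIC 11q13.1, with 47 peaks (18.8 per Mb). Peak density followed a similar order of chromosomes in the 3 libraries, with Spearman's rho across 24 chromosomes of 0.99 for NFIC with SMRC1, 0.97 for SATB1 with SMRC1 and 0.97 for SATB1 with NFIC. Pearson's r was 0.985, 0.958 and 0.959, and 0.984, 0.919 and 0.929 without the 2 chromosomes farthest from the median. All adjusted permutation p were 1.8e-05 over 12 relations. Counted per protein-coding gene in place of per Mb, rho was 0.93 for NFIC with SMRC1, 0.63 for SATB1 with SMRC1 and 0.74 for SATB1 with NFIC.

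Chromosomes 2, 6, 14, 16, 17 and 20 carried more SATB1 peaks for their gene number. They had 0.198 to 0.317 SATB1 peaks per protein-coding gene, and the other 16 autosomes 0.119 to 0.163, a ratio of 1.71. For SATB1 peaks with a fold of at least 5 the ratio was 0.792 (95% interval 0.599 to 1.04), and below that fold it was 1.83 (1.70 to 1.97), a split added after seeing the data. Over all peaks the ratio was 1.40 for NFIC and 1.24 for SMRC1. The same chromosomes had a higher control background at SMRC1 peaks, from 1.25 times that of the other autosomes on chromosome 14 to 1.74 times on chromosome 20. Chromosome 19, outside the set, was also at 1.25, and at 1.24 by the NFIC list, but at 0.926 by the SATB1 list. The correlations below use the background at SMRC1 peaks only, and may depend on that choice. This set was chosen after the values per chromosome had been seen, so no test of the difference is given. The same 6 chromosomes are those gained in HepG2 by its textbook karyotype, but copy number was not measured here. Across the 22 autosomes SATB1 peaks per gene rose with the background (r = 0.895, adjusted permutation p = 1.8e-05; rho = 0.47, adjusted p = 0.039), with r = 0.792 without the 2 chromosomes farthest from the median. The relation rested on these 6 chromosomes, and within the other 16 autosomes it was not seen (r = -0.33, adjusted permutation p = 0.24; rho = -0.37, adjusted p = 0.19). NFIC peaks per gene had r = 0.480 (adjusted permutation p = 0.036) and rho = 0.22 (adjusted p = 0.36) with the background across the 22 autosomes, and r = 0.090 without the 2 farthest chromosomes. In the other 16 the values were r = -0.53 (adjusted permutation p = 0.051) and rho = -0.48 (adjusted p = 0.079), with r = -0.13 without the 2 farthest. SMRC1 peaks per gene had r = 0.14 across the 22 autosomes (adjusted permutation p = 0.55) and fell with it in the other 16 (r = -0.67, adjusted permutation p = 0.012; rho = -0.72, adjusted p = 0.0034), with r = -0.41 without the 2 chromosomes farthest from the median. The set was picked partly on SATB1 peaks per gene, which limits the range left in the other 16.

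**Figure D3:**
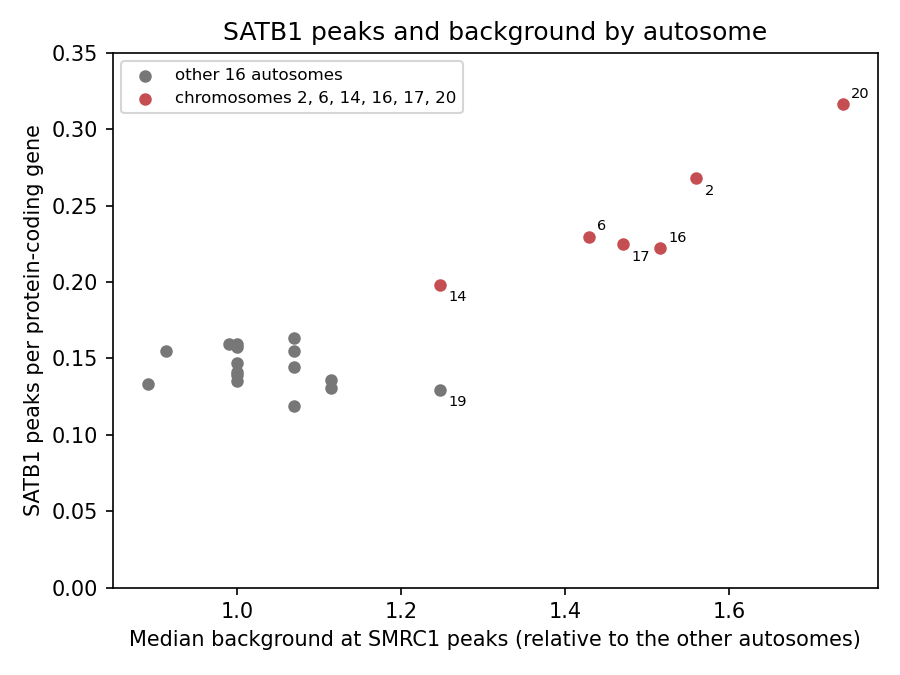
SATB1 peaks per protein-coding gene against the median control background at SMRC1 peaks, relative to the other autosomes, with 1 point per autosome. The 6 chromosomes in red lie between 0.198 and 0.317 peaks per gene, above the other 16.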

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

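The test of weak sites among SATB1 peaks, the comparison within the other chromosomes, the moved peaks and the odds ratio within deciles of strength were set before their results were seen; the remaining tests here were chosen only after the result, or values that nearly fixed it, had been seen, and all were added after seeing the data.

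Fold moved in opposite directions between the libraries when shared and other peaks were compared. Shared peaks ranked higher by fold in the SMRC1 list and lower in the other lists, and the contrasts differed by 50.9 percentile points between SMRC1 and NFIC and by 48.3 between SMRC1 and SATB1, each list being 1 library, so that a difference between antibodies was not tested. NFIC peaks at SMRC1 sites had a median fold of 4.19 (4.14 to 4.24), against 5.60 (5.49 to 5.65) elsewhere. As to fewer NFIC reads, the median summit of the listed peaks held 1.6 times as many reads at SMRC1 sites (1.6 to 1.71), not fewer. The reads were recovered from the fold and the p-value, and the higher −log10 q and lower fold already seen left little room for another outcome. The ratio is therefore no independent test. A larger share on chromosomes 2, 6, 14, 16, 17 and 20, whose background was higher, is argued against as the whole cause, since the difference in median fold was -1.30 (-1.40 to -1.21) within the other chromosomes. Since the fold is reads over background, a lower fold with more reads goes with a higher local background by arithmetic. The recovered median was 2.66 times as high at SMRC1 sites (2.44 to 2.66), which is likewise no independent test. Why the background was higher there stays open, and whether it reflects open chromatin in the control was not tested.

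The control background recovered from the lists, which is the denominator of the fold and enters each p-value, was uneven between chromosomes. At chromosome 20 it was 1.74 (SMRC1 list), 2.04 (SATB1 list) and 1.76 (NFIC list) times that of the other autosomes. On chromosomes 2, 6, 14, 16, 17 and 20 the SATB1 list held 1.71 times as many peaks per protein-coding gene (1.65 to 1.74 leaving out each autosome in turn). These are the 6 autosomes with the highest such values. Picking the highest 6 in each of 10000 draws of peaks spread by gene number gave at most 1.25. This argues against gene number with counting error alone as the whole cause. The draws held no other variation between chromosomes, so they cannot tell what sets these 6 apart. Their median SATB1 fold was 0.880 times that of the other autosomes (0.867 to 0.905), and among SATB1 peaks with a fold of at least 5 the ratio per gene was 0.792 (0.599 to 1.04; 72 and 227 peaks), against 1.83 (1.70 to 1.97) below that fold. Neither value separates extra chromosome copies or an excess of weak sites from an even excess, since the background at SATB1 peaks was 1.56 times as high on these chromosomes and may itself lower the fold; these stay open, and copy number was not measured here.

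Most SATB1 peaks lay at SMRC1 sites. Regional density of both lists is argued against, since moving SATB1 peaks by 10 to 50 kb left 4.28% of the overlap (3.52 to 5.05, 2 SD either way). Collection of SATB1 reads at any site open to ChIP cannot be told apart from binding at the same sites. Within deciles of SMRC1 strength the odds ratio of a SATB1 peak with against without an NFIC peak was 1.12 (1.02 to 1.23), which both predict. No biological explanation was tested for these 3 patterns.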

How the results depend on the processing

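The moved peaks, equal list sizes, omission of bands, ranking by fold and omission of 6 chromosomes were chosen after seeing the data. Of 63 alternatives over 19 results, 43 kept direction and size or side of the threshold, 18 moved and 2 reversed. Size was judged only for peak numbers, widths and shares. The overlap excess, the correlations and the rank differences counted as kept when direction and a permutation p under 0.05 held, whatever their size. At a −log10 q of at least 10 the lists fell to 12871 (SMRC1), 456 (SATB1) and 6314 (NFIC) peaks, with median widths of 827, 520 and 613 bp. That setting gave shares of 38.5% for NFIC at SMRC1 sites, 71.3% for SATB1 at SMRC1 sites and 20.0% for SATB1 at NFIC sites. In the same order the shares were 50.1%, 76.7% and 24.9% with 50% of the shorter peak covered, 39.1%, 54.3% and 19.6% with centres within 200 bp, and 20.1%, 20.2% and 8.71% with equal numbers of peaks. Stricter overlap lowers shares by construction. With equal numbers the SATB1 list was unchanged and the other lists were cut to its size, so the SATB1 shares could only fall. For NFIC at SMRC1 sites with equal numbers, and for the stricter −log10 q, the cause was not tested. The excess over random placement held in every alternative run, with the lowest values, 14.6-fold to 36.9-fold, when peaks were moved by 10 to 50 kb. Ranked by fold, shared peaks lay lower for SATB1 (-23.7 points) and NFIC (-26.4 points); the cause was not settled. Placement matched to transcription start sites and the promoter, motif and gene-list alternatives were not run. No paired analysis was possible because each antibody had 1 library. The absolute depth is unknown, so weak sites missed for lack of reads cannot be counted, least of all for SATB1.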

Other observations

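All tests and choices in this part were made after the data were seen. Clusters of SMRC1 sites were counted without an expected number from random placement. Joined within 12.5 kb, the SMRC1 peaks formed 18423 regions, of which 27 held 10 or more peaks. The region with the most SMRC1 peaks lay on chromosome 2 at 43371394 to 43458914 (p21), with 16 SMRC1, 7 NFIC and 4 SATB1 peaks. Next came chromosome 6 at 47062063 to 47169303 (p12.3), with 15 SMRC1, 3 NFIC and 0 SATB1 peaks. Of the 27, 51.9% lay on chromosomes 2, 6, 14, 16, 17 and 20, which held 32.4% of all SMRC1 peaks.

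The widest SATB1 peak spanned 4453 bp on chromosome 2 at 21227712 to 21232164 (p24.1), with a fold of 8.67, and overlapped no peak of either other library. The highest NFIC fold, 50.2, was on chromosome 16 at 1321178 to 1322746 (p13.3), which also overlapped neither of the other lists. It rested on a low background, with 174 summit reads over 2.46 control fragments. The NFIC peak of highest −log10 q had 412 reads over 9.55. SATB1 and NFIC both had peaks on chromosome 21 p11.2, a variable band. The SATB1 peak at 9825333 to 9826406 had a fold of 3.60, and the NFIC peak at 9825304 to 9826443 a fold of 3.24. The main lists were not filtered here for artifact-prone regions, so whether these peaks reflect binding was not tested.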
